A study of Caenorhabditis elegans with 2 samples.

How the data were processed

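Late C. elegans embryos that carried an eGFP-tagged PAX-1 transgene were profiled by ChIP-seq in 2 biological replicates, which the labels number 1 and 2. Both belong to 1 group, so no comparison between groups was possible. The labels call the replicates biological and do not say how the cultures were kept apart. The labels name a fragment size range and give no extraction protocol.

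The starting point was 8 peak lists in the narrowPeak layout, 4 on each of the builds ce10 and ce11: 1 list per replicate, 1 called on both replicates pooled, and 1 thresholded list. Per the file listing deposited with the samples, the replicate and pooled lists hold peaks and background and were made from alignments and a control alignment as input for the irreproducible discovery rate (IDR) procedure. The thresholded list, which the authors name optimal, was derived from the 2 replicate lists and the pooled list. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal value of each peak (column 7) is the authors' own, on a scale that the deposited listing does not state, and was used only to rank and describe peaks within a list. The −log10 q of each peak (column 9) is also the authors' deposited value. Its median in the pooled list was 0.0382, so most pooled peaks are weak. A control with more or fewer copies of a region than the sample can add or remove peaks there. No list gives read counts, so the depth per sample is unknown and no interval for counting error of reads was computed. The number of unmatched columns with values per sample was 0.

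Coordinates were used on ce11 only, with the Ensembl 115 annotation and the RefSeq sequence of the same assembly, and ce10 lists entered counts and widths only. No coordinate was converted between builds. Peaks were sorted by signal. The 714 thresholded peaks were compared with the 29179 pooled peaks that overlapped none of them, since these could have passed the authors' threshold and did not. Shares were compared with Fisher's exact test (two-sided), with 95% intervals of the odds ratio by Woolf's method with 0.5 added to each cell, and with Benjamini-Hochberg adjustment within each family (6 chromosomes, 20 gene lists, 2080 hexamers and 14 motifs, at 0.05). Neighbouring peaks are not independent, so these p-values describe the peak lists and not variation between animals.

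A summit was called proximal within 500 bp of a protein-coding transcript start. A gene was given a peak when its start was the nearest and within 1000 bp. The universe for gene lists was the 9308 genes given any pooled peak. Of the list members written down by name, ram-4 and daf-21 matched no annotated symbol. Hexamers and motifs were searched on both strands in windows of 75 bp on each side of the summit. Background windows were drawn from the lower pooled peaks in G+C steps of 5 percentage points, up to 5 per thresholded peak, with a fixed seed. 1 mitochondrial window ran past the end of the sequence and was left out. Replicate overlap used the 714 highest peaks of each replicate, at least 1 bp of overlap, and 1000 random placements on the same chromosome.

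The main tests, gene lists, motifs and the rule for named genes were fixed before the data were examined. The test of upstream shares, the rank correlation and the tests under Other observations were not part of that plan. Named were pax-1, the genes assigned to the 25 highest thresholded peaks that overlapped a peak in both replicate lists, up to 6 members of each list that passed, up to 2 members of each other list by signal, Pax family members with a thresholded peak (there were 0), the 8 hexamers with the smallest p, and every motif. Nearest genes of unassigned peaks among those 25 are given for orientation. Other names were chosen after their values were seen. The lists covered markers of pharynx, body wall muscle, intestine, epidermis, neurons, glia, excretory system and germline, the Pax, homeobox, nuclear hormone receptor and basic helix-loop-helix families, and Wnt pathway, ribosomal protein, proteasome, collagen, histone, chaperone, vacuolar ATPase and apoptosis genes.

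Alternatives were the 357 thresholded peaks with the highest signal, the 714 highest peaks of either replicate in place of the thresholded list, other distances, windows, overlaps and backgrounds, and the other build. An alternative without mitochondrial peaks was added after seeing the data. The steps were tested on simulated data. With no effect planted, 0 of 2080 hexamers and 0 of the gene lists passed. A hexamer planted in 15% of windows ranked 1 of 2080, with 5 other hexamers past the threshold, and a planted list with peaks at 22 of its 40 genes was called among 9308 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.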

Results

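Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where PAX-1, a transcription factor with a paired DNA-binding domain, sat on the genome of late Caenorhabditis elegans embryos. The protein carried an enhanced green fluorescent protein (eGFP) tag and came from a transgene inserted in an unc-119 mutant strain. Whole animals of both sexes were pooled, and the series holds 1 group with 2 biological replicates. There was no untreated or untagged group. A control alignment entered the authors' peak calls and was not analysed here. The files give no read counts, so the depth of each sample is unknown, and the p-values below compare sets of peaks within this pooled data set, not replicate animals.

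On the ce11 build, the authors' list for replicate 1 held 30000 peaks, that for replicate 2 held 29397, and the list called on the pooled replicates held 30000. Their thresholded list held 714 peaks, which were the 714 pooled peaks with the highest signal value. The signal in that list ran from 58.3 to 1574, with a median of 75.01, and 694 of the peaks were 344 bp wide. All 714 shared a −log10 q of 1.85, so only the signal ranked them. On ce10 the thresholded list held 644 peaks, 622 of them 350 bp wide. The split over chromosomes I, II, III, IV, V and X was 155, 111, 128, 100, 100 and 102 peaks on ce11 and 144, 97, 115, 91, 87 and 92 on ce10, and 18 peaks lay on mitochondrial DNA in either build. Positions below are on ce11.

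The gene that encodes the tagged protein was examined first. No thresholded or pooled peak lay in pax-1 (WBGene00003937, chromosome V, 8224934 to 8226116, plus strand) or within 20 kb of it, where the mean density of chromosome V would give 10.04 pooled peaks. The nearest pooled peak was 20.9 kb away and the nearest thresholded peak 274 kb away. Replicate 1 had 4 peaks and replicate 2 had 2 within 20 kb, the highest at rank 10530 and rank 22318 of their lists, and neither had a peak within 5 kb. The stretch between neighbouring pooled peaks that held pax-1 ran from 8195600 to 8247029. At 51.4 kb it was the fifth longest of 4848 such stretches on chromosome V, whose median was 2.10 kb, and it overlapped 15 protein-coding genes.

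**Figure D1:**
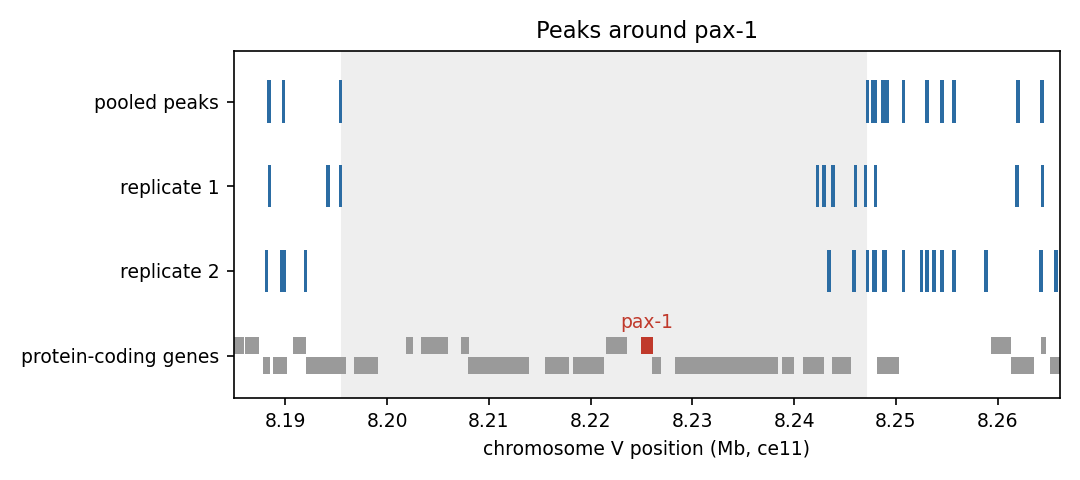
Peaks of the pooled list and of each replicate (blue bars, drawn to scale) and protein-coding genes (grey, upper row plus strand, lower row minus strand) by position on chromosome V in Mb. The shaded stretch of 51.4 kb around pax-1 (red) holds no pooled peak, and the peaks of replicates 1 and 2 inside it lie at its right end.

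The next question was whether the replicates placed their highest peaks at the same sites. Of the 714 highest peaks of replicate 1, 302 (42.3%) overlapped 1 of the 714 highest of replicate 2 by at least 1 bp, and 306 (42.9%) did so in the other direction. Peaks moved to random places on the same chromosome overlapped in 0.687% of cases on average and in 1.54% at most (one-sided permutation test, p = 0.000999, the smallest that 1000 draws can give). Random placement did not keep the closeness to protein-coding starts, within 500 bp of which 56.0% and 56.9% of these peaks of replicates 1 and 2 lay. The test therefore does not separate agreement on sites from a shared preference for starts. Nearly all thresholded peaks were present somewhere in each replicate's full list, 697 in replicate 1 and 705 in replicate 2. Among the 714 highest of each, 544 thresholded peaks (76.2%) had an overlap in replicate 1 and 421 (59.0%) in replicate 2. Across the 686 nuclear thresholded peaks present in both lists, the ranks in replicates 1 and 2 had a Spearman's rho of 0.151. That value is across peaks, which are not independent replicates. The peaks were also chosen by the pooled signal, which draws on both replicates. Such a choice can lower the correlation between replicates, so rho does not measure their agreement over the whole lists.

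Thresholded peaks lay close to the starts of protein-coding genes. A summit within 500 bp of an annotated protein-coding transcript start was found for 419 of 714 thresholded peaks (58.7%) and for 7948 of 29179 lower pooled peaks that overlapped none of them (27.2%). The odds ratio was 3.79 (95% interval 3.26 to 4.41, Fisher's exact test, two-sided, p = 2.63e-67), and 23.1% of the nuclear genome lies within that distance. These counts include mitochondrial peaks, as do the upstream counts below. On the nuclear chromosomes the share was 405 of 696 (58.2%) against 27.2%, with an odds ratio of 3.72 (95% interval 3.19 to 4.33). The median distance was 309.5 bp for thresholded and 1209 bp for lower peaks. Of the 419 proximal summits, 379 (90.5%) were upstream of the start, against 61.2% of the proximal lower peaks (odds ratio 6.02, 95% interval 4.29 to 8.25, Fisher's exact test, p = 4.46e-40). In 4 equal parts of the thresholded list, from the highest to the lowest signal, the proximal share was 56.4%, 59.2%, 58.4% and 60.7%.

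**Figure D2:**
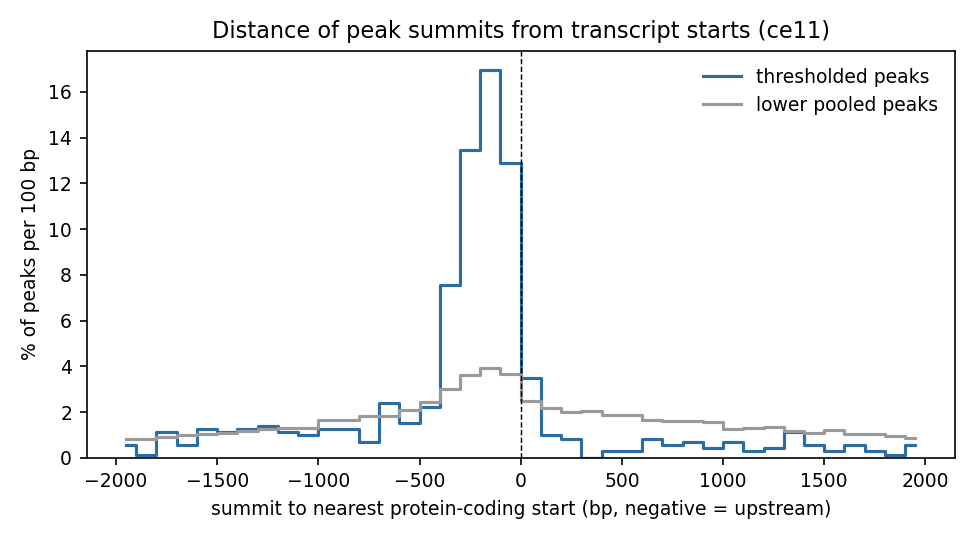
Percent of peaks per 100 bp by the distance of the summit from the nearest protein-coding transcript start (bp, negative upstream), for the 714 thresholded peaks (blue) and the 29179 lower pooled peaks (grey). The thresholded peaks gather upstream of the start, where 379 of the 419 proximal summits lie.

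The 25 highest thresholded peaks found in the lists of both replicates reached down to rank 36, and 13 of them had a protein-coding start within 1000 bp. The highest of these, with a signal of 202.7, lay on chromosome III from 8447071 to 8447231, in intergenic sequence 184 bp upstream of rpn-3, which encodes a subunit of the proteasome cap. A start of hsp-110, a chaperone gene, was also within 1000 bp of this summit. Next came intergenic peaks 282 bp upstream of rpl-3 (chromosome III, 3867400 to 3867743, signal 194.2), which encodes a protein of the large ribosomal subunit, and 270 bp upstream of R107.5 (signal 193.5). The peaks upstream of sec-61.G, a subunit of the protein translocation channel, tba-2, an alpha tubulin, and rfc-4, a subunit of the clamp loader of DNA replication, had signals of 193.0, 191.3 and 191.0. A start of eef-1A.1, a translation elongation factor gene, was also within 1000 bp of the rfc-4 summit. The peak 177 bp upstream of cdc-48.1, an AAA ATPase of protein degradation, had a signal of 185.3. Peaks assigned to lntl-1 and to zfp-1, a zinc finger protein gene, lay in introns with signals of 181.3 and 180.6. The remaining assigned genes were egl-30, which encodes a G protein alpha subunit (68 bp, signal 172.0), ftt-2, a 14-3-3 protein gene (433 bp), T26A8.4 (59 bp, signal 168.4) and dld-1, the dihydrolipoamide dehydrogenase gene (188 bp, signal 166.4). Their peaks were intergenic and upstream of the start. Starts of C53H9.4 and rpl-27 were also within 1000 bp of the egl-30 summit. The summits at R107.5, sec-61.G, T26A8.4 and dld-1 had starts of cls-2, F32D8.13, pdtf-1 and nspg-9 within 1000 bp, in that order.

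Of the other 12 peaks, 2 were mitochondrial, at 13020 to 13320 and 13642 to 13794 of the molecule, with signals of 918.9 and 177.4. The highest nuclear peak lay on chromosome X from 16929627 to 16929950, with a signal of 650.8, in intergenic sequence 5841 bp from the start of C30E1.4. It was followed by an intergenic X peak from 3306942 to 3307190, with a signal of 386.8, 2706 bp from the start of F11D5.7. The intergenic X peaks at 11094054 to 11094397, 806631 to 806721 and 13700665 to 13701008 had signals of 181.6, 180.9 and 177.1 and lay 3960 bp, 3893 bp and 6070 bp from the starts of W02H3.3, gtr-1 and K02D3.1. Intronic peaks nearest to chtb-1, ptr-19 and mnk-1 had signals of 225.4, 181.3 and 172.2. An intergenic peak nearest to T02E9.6 had a signal of 177.2, and a peak in a non-coding RNA gene 2698 bp from the start of the actin gene act-1 had a signal of 180.9.

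Genes for ribosomal proteins, the proteasome and chaperones held thresholded peaks more often than other genes. A gene was counted when its start was the nearest protein-coding start to a summit and within 1000 bp of it. By that rule 474 of the 9308 genes with any pooled peak (5.09%) had a thresholded peak. Of the cytosolic ribosomal protein genes, 25 of 47 (53.2%) had one (odds ratio 22.3, 95% interval 12.5 to 39.5, Fisher's exact test, adjusted p = 2.66e-19 over 20 lists). The highest were rpl-3, rps-12, rpl-15, rpl-35, rps-28 and rps-22, with signals of 194.2, 158.0, 154.3, 136.2, 128.7 and 109.2. Their summits were intergenic and upstream of the start, at 282, 139, 349, 456 and 440 bp for the first 5. The summits at rps-12, rpl-15, rps-28 and rps-22 also had the start of another gene within 1000 bp. With the 714 highest peaks of replicate 1 alone 29 of 49 genes had a peak (odds ratio 28.5), and with those of replicate 2 alone 19 of 50 (odds ratio 12.6, exact test, adjusted p = 9.45e-12).

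Of the proteasome genes, 6 of 19 (31.6%) had a thresholded peak (odds ratio 8.70, 95% interval 3.54 to 23.2, Fisher's exact test, adjusted p = 0.00260). They were rpn-3, rpt-2, rpn-11, rpn-8 and rpn-5 of the regulatory particle and pas-4 of the core, with signals of 202.7, 77.5, 70.9, 70.7, 68.1 and 66.6. Each of these 6 summits also had another protein-coding start within 1000 bp, so the assignment rests on the nearest start. In the same order these were hsp-110, aps-1, K07D4.2, mrps-6, scc-1 and rpb-3. The rpt-2 and rpn-5 peaks ranked 137 and 405 in replicate 1 and only 28983 and 5267 in replicate 2, while rpn-8 ranked 840 and 212. With the 714 highest peaks of replicate 1 or 2 alone the proteasome odds ratio was 6.68 and 7.99 (exact test, adjusted p of 0.0147 and 0.0239). Of the heat shock and chaperone genes, 8 of 44 (18.2%) had one (odds ratio 4.20, 95% interval 2.07 to 9.32, Fisher's exact test, adjusted p = 0.00995). The highest were hsp-1, a heat shock protein of the Hsp70 class (signal 137.2), the DnaJ-domain genes dnj-24, dnj-13 and dnj-29 (107.4, 84.7 and 70.9), the co-chaperone gene sti-1 (65.0) and dnj-9 (63.6). Of these, the dnj-13 and dnj-29 summits also had the start of another gene within 1000 bp. In the 357 thresholded peaks with the highest signal, the odds ratios were 4.61 for the proteasome and 2.87 for chaperones, and the adjusted p of both was 0.388. The chaperone odds ratio was 2.15 with the 714 highest peaks of replicate 2 alone (exact test, adjusted p = 0.530), 9.15 when every gene with a start within 1000 bp was counted (20 of 51, adjusted p = 3.12e-10) and 6.42 against all protein-coding genes.

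No other list passed the threshold. Histone genes came nearest, with 4 of 19 (21.1%, odds ratio 5.004, Fisher's exact test, adjusted p = 0.0699), and they passed it with either replicate alone (odds ratio 6.22, adjusted p = 0.0378 for replicate 1, and 11.1, adjusted p = 0.00350 for replicate 2) and in the 357 peaks with the highest signal (10.6, adjusted p = 0.0110). Against all protein-coding genes the odds ratio of the histone list was 2.43 (4 of 72, exact test, adjusted p = 0.262), and with starts within 2000 bp it was 4.64 (adjusted p = 0.0692). With starts within 500 bp it was 7.03 (exact test, adjusted p = 0.0295). When every gene with a start within 1000 bp was counted it was 6.57 (8 of 25, exact test, adjusted p = 0.00106). The highest of them were at his-61 (signal 136.7) and his-32 (121.2), whose summits each had another histone gene start, his-62 and his-31, within 1000 bp. Of the body wall muscle markers, 3 of 15 had a peak (exact test, adjusted p = 0.151), among them the actin gene act-4 (signal 88.5) and unc-112, a muscle attachment gene (64.4). Of the vacuolar ATPase genes, 2 of 10 had one, vha-12 and vha-9 (exact test, adjusted p = 0.296), and of the Wnt pathway genes 2 of 18, the Dishevelled genes dsh-2 and mig-5 (adjusted p = 0.662). The highest peaks among 5 of 143 nuclear hormone receptor genes were at nhr-183 and nhr-44. The homeobox list had 1 of 53 (ceh-38), the basic helix-loop-helix list 1 of 22 (mdl-1) and the epidermis list 1 of 13 (ajm-1, an apical junction gene), with an adjusted p of 1 for each of these 4 lists.

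No thresholded peak was assigned to the 10 pharynx, 9 intestine, 20 neuron, 4 glia, 11 excretory system, 4 germline, 13 apoptosis, 39 collagen or 5 Pax family genes that had any pooled peak. These lists are small for an overall share of 5.09%, and the upper 95% bounds of their odds ratios ran from 3.82 for collagen to 38.5 for glia and germline. A higher share in them was therefore not excluded. The distance rule assigned 490 of the 714 thresholded peaks (68.6%), and the other peaks counted for no list. The peak at rank 111, 5072 bp from the start of its nearest gene, pha-4, was left out in this way. With starts within 2000 bp the pharynx list had 0 of 13 and the collagen list 1 of 55. Peaks farther away were not tested against the lists, so the absence holds only for peaks near a start.

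**Figure D3:**
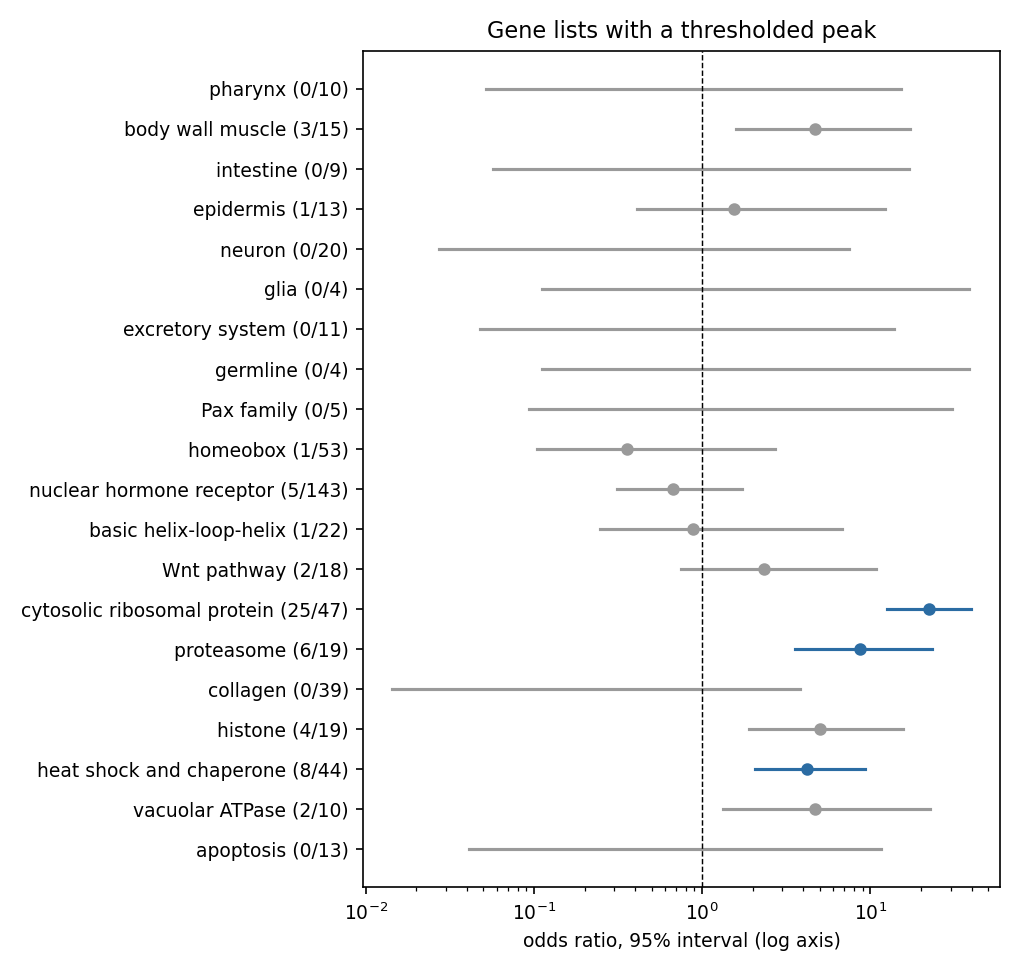
Odds ratio (log axis) with 95% interval for each of 20 gene lists against the other genes with any pooled peak, with members with a thresholded peak over members with any pooled peak in parentheses. Blue marks an adjusted p under 0.05, reached by the ribosomal protein, proteasome and chaperone lists, and a line without a point has no member with a thresholded peak.

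Chromosome I held more thresholded peaks than lower pooled peaks, 155 of 714 (21.7%) against 16.8% (odds ratio 1.37, 95% interval 1.15 to 1.65, Fisher's exact test, adjusted p = 0.00503 over 6 chromosomes). Chromosome X held fewer, 102 (14.3%) against 17.8% (odds ratio 0.771, 95% interval 0.627 to 0.956, exact test, adjusted p = 0.0299), as did IV (14.01% against 18.4%, adjusted p = 0.00706) and V (14.01% against 17.1%, adjusted p = 0.0452). Chromosomes II and III did not pass the threshold (adjusted p of 0.330 and 0.129). None of these 4 differences passed the threshold in the 357 peaks with the highest signal (exact tests, adjusted p of 0.866 for I, 0.397 for IV and X and 0.229 for V), where the odds ratio of I was 0.940. In replicate 1 alone I passed, and X, IV and V did not (adjusted p of 0.0569, 0.127 and 0.295). In replicate 2 alone all 4 passed (exact tests, adjusted p of 0.00107 for I and V, 0.0190 for IV and 0.0368 for X). Without the mitochondrial peaks, in a test chosen after seeing the data, X and V did not pass (adjusted p of 0.0694 and 0.0709).

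Peaks over tRNA genes were more common in the thresholded list, 16 of 714 (2.24%) against 168 of 29179 (0.576%), with an odds ratio of 3.96 (95% interval 2.44 to 6.78, Fisher's exact test, p = 9.75e-06). On the nuclear chromosomes it was 11 of 696 (odds ratio 2.79, exact p = 0.00317), and in replicate 1 alone 9 of 714 (odds ratio 1.94, p = 0.0595). Against the lower-signal part of the pooled peaks alone, the odds ratio was 7.43 (exact p = 1.11e-08). As values beside this test, snRNA genes were overlapped by 6 thresholded peaks (0.840%) and 0.0994% of lower peaks, and snoRNA genes by 7 (0.980%) and 0.428%. The 3 thresholded peaks over rRNA genes were mitochondrial.

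Short sequences at the summits differed from those at lower peaks of the same G+C content. Windows of 151 bp around the thresholded summits had a mean G+C of 43.3%, against 32.2% around all lower summits, so 3556 background windows matched on G+C were compared with 713 thresholded windows. Of 2080 hexamers, each counted with its reverse complement, 163 were more frequent at thresholded summits and 131 less frequent (Fisher's exact test, adjusted p under 0.05). The hexamer with the smallest p, AGAGAC, occurred in 30.3% of thresholded and 14.5% of background windows (odds ratio 2.57, 95% interval 2.14 to 3.10, exact test, adjusted p = 1.11e-18). CGTCTC was found in 27.6% against 13.7%, ACGCAG in 23.8% against 11.4%, and GACGCA in 22.3% against 10.7%. CGAGAC was found in 17.5% against 7.73%. The hexamers of G and C, or nearly so, were AGCGCG (15.99% against 6.05%), GAGCGC (16.3% against 6.496%) and GCGCGC (13.3% against 5.09%). The odds ratios of these 8 ran from 2.41 to 2.96. The background was matched on G+C and not on position. Lower peaks were proximal less often than thresholded ones (27.2% against 58.7%), and nuclear lower peaks were in introns more often (38.5% against 17.1%). Differences in these hexamers, and in the fixed motifs below, therefore cannot be told apart from a difference in position relative to genes.

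Paired domains of PAX1 and PAX9 are known to contact a core of GTCACGC. This core occurred in 13 of 713 thresholded windows (1.82%) and 32 of 3556 background windows (0.900%), an odds ratio of 2.05 (95% interval 1.10 to 3.96) that did not pass the adjustment over 14 motifs (Fisher's exact test, adjusted p = 0.145). For the 357 peaks with the highest signal the background was matched anew. There the core was found in 9 of 356 windows (2.53%) against 9 of 1780 (0.506%), an odds ratio of 5.10 (exact test, adjusted p = 0.00750). These counts are small, and the background share was below the 0.900% above, which raised the odds ratio. The odds ratio was 2.53 in replicate 1 alone (exact test, adjusted p = 0.0273), 1.83 in replicate 2 alone (adjusted p = 0.496) and 3.02 in windows of 150 bp on each side (exact test, adjusted p = 0.00276). The shorter core GTCACG, which every GTCACGC contains, was found in 43 thresholded windows (6.03%) against 3.71% (odds ratio 1.66, 95% interval 1.18 to 2.39, exact test, adjusted p = 0.0477). That call was lost in replicate 1 alone (odds ratio 1.44, exact test, adjusted p = 0.184), in replicate 2 alone (odds ratio 1.57, adjusted p = 0.259) and in windows of 50 bp on each side (odds ratio 1.82, adjusted p = 0.0703). In the 357 peaks with the highest signal it was found in 6.74% against 2.47% (odds ratio 2.85, exact test, adjusted p = 0.00239), so the background share moved more than that of thresholded windows.

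The GAGA repeat GAGAGAGA was found in 68 thresholded windows (9.54%) against 6.21% (odds ratio 1.59, 95% interval 1.20 to 2.12, Fisher's exact test, adjusted p = 0.0261), with the call lost in the windows of 50 bp on each side (odds ratio 1.37, adjusted p = 0.312). The E2F site TTCCCGC was in 4.63% against 2.92% (exact test, adjusted p = 0.122) and the E-box CACGTG in 2.10% against 3.43% (adjusted p = 0.186). In replicates 1 and 2 alone the E2F odds ratio was 1.40 and 0.878 (exact test, adjusted p of 0.210 and 0.764). The T-box site AGGTGTGA was in none of the thresholded windows and in 19 background windows (exact test, adjusted p = 0.165). The homeodomain core TAATTA, the GATA site TGATAA, the forkhead site TGTTTAC, the E-box CAGCTG, the AP-1 site TGACTCA, the Sp1 or KLF site GGGCGG, the nuclear receptor site AGGTCA and the heat shock element pair GAANNTTC had odds ratios from 0.759 to 1.19, with adjusted p from 0.522 to 0.755. Of these, TGATAA was less frequent at the summits of replicate 1 alone (odds ratio 0.619, exact test, adjusted p = 0.0273), and not past the threshold in replicate 2 alone (odds ratio 0.786, adjusted p = 0.457). In replicate 2 alone TGTTTAC and CAGCTG had odds ratios of 1.45 and 1.27 (exact test, adjusted p of 0.496 and 0.514), against 0.771 and 0.759 for the thresholded list. Without matching on G+C, TAATTA and GAANNTTC turned from odds ratios of 1.07 and 1.05 to 0.433 and 0.618 (exact test, adjusted p of 2.51e-06 and 0.000634).

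**Figure D4:**
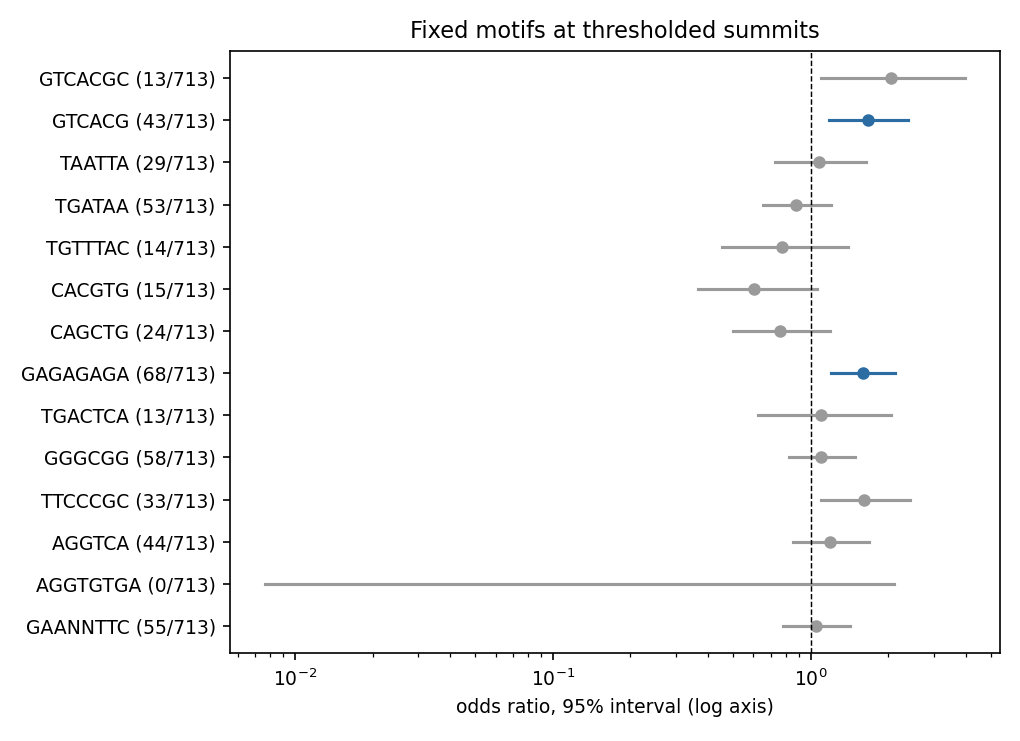
Odds ratio (log axis) with 95% interval for each of 14 fixed motifs in windows of 75 bp on each side of the summit, thresholded peaks against background matched on G+C, with thresholded windows that hold the motif over all of them in parentheses. Blue marks an adjusted p under 0.05, reached by GTCACG and GAGAGAGA, and the line without a point has no thresholded window with the motif.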

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

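The alternative without mitochondrial peaks was chosen after seeing the data. The overlap of the replicates stayed above random placement, and the proximal share stayed higher in thresholded peaks, under every alternative run (36.97% to 43.4% overlap, with 37.8% against 19.02% at random for the full lists; odds ratios of 2.72 to 4.40). The lower share on X (odds ratio 0.771) missed the threshold in the 357 peaks with the highest signal (0.843), without mitochondrial peaks (0.794) and in 1 of the replicates taken alone (0.785 to 0.792). The tRNA odds ratio ranged from 1.94 to 3.77 over the single replicates, missed the threshold in replicate 1, and was 7.43 against the lower-signal part of the pooled peaks. The number of hexamers past the threshold, 294, was 132 in the 357 peaks with the highest signal, where fewer windows were tested, 1085 without matching on G+C and 791 against flanks of the same summits, whose G+C was lower (35.8%). The 8 named hexamers kept direction and threshold in all 64 comparisons. They had been picked by the smallest p, and the alternatives reuse many of the same peaks, so this is not independent support. Of the fixed motifs, 2 passed: 0 in windows of 50 bp on each side, 1 to 3 over the single replicates, and 9 both without G+C matching and against flanks. Of the comparisons of named lists, hexamers and motifs that had passed, 7 missed the threshold under an alternative and 0 reversed. Of 232 that had not passed, 29 crossed an odds ratio of 1 and 23 passed under an alternative, 5 for the histone list and 18 for motifs. Without G+C matching and against flanks, these motifs were GTCACGC, the GATA, Sp1 or KLF and E2F sites, the nuclear receptor site, the homeodomain core and the heat shock element pair. In 4 of these comparisons the odds ratio changed sides: from 1.07 to 0.433 and 0.466 for the homeodomain core, and from 1.05 to 0.618 and 0.662 for the heat shock element pair. The GATA site (odds ratio 0.878) fell to 0.504 and 0.473 there, and to 0.619 in replicate 1 alone. The number of lists that passed (3) stayed between 2 and 4, with the ribosomal protein list among them each time. The thresholded list held 644 peaks on ce10. Causes not named here were not tested. The unknown depth leaves open how much of the spread between replicates is counting error.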

Other observations

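The tests for extra copies around pax-1, for a longer sequence behind the hexamers and for GTCACG in whole peaks were chosen after the result they measure, or a related one, was seen. The tests on mitochondrial spacing and on the X element were devised after the peak positions were seen, and the former replaced a test on coverage. The design has 1 group, so no biological difference between groups was tested.

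By summit position, 482 of 696 nuclear thresholded peaks (69.3%) were intergenic, against 41.98% of lower pooled peaks and 33.3% of the nuclear genome (odds ratio 3.11, 95% interval 2.64 to 3.66, Fisher's exact test, adjusted p = 1.10e-45 over 6 classes). Coding sequence held 4 (0.575%, odds ratio 0.0520, 95% interval 0.0231 to 0.148), and introns 17.1%, against 38.5% of lower peaks. Non-coding RNA genes and pseudogenes held 57 (8.19% against 2.76%, odds ratio 3.15, exact test, adjusted p = 2.94e-12). Of these 57 summits, 53 were in genes annotated as ncRNA and 0 in pseudogenes, while 361 of the 804 such lower summits were in pseudogenes. Of the 419 proximal thresholded peaks, 146 (34.8%) had the starts of more than 1 gene within 500 bp. Peaks with over 50% of soft-masked (repetitive) bases made up 15.7% of the thresholded and 34.7% of the lower list.

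The 13 thresholded peaks with the paired-domain core GTCACGC, chosen after seeing the data, ranged from rank 13 to rank 656. The highest lay in an intron nearest to chtb-1 (chromosome III, 9353844 to 9354187). Others lay 7 bp upstream of the start of eef-2, a translation elongation factor gene, 109 bp upstream of atg-16.1, an autophagy gene, 232 bp upstream of eif-3.I, a translation initiation factor gene, 276 bp upstream of vps-4, an endosomal sorting gene, and in an intron nearest to pac-1 (1642 bp from its start).

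Of the 25 highest nuclear thresholded peaks, 6 were on X and 5 of these lay over 2 kb from any protein-coding start. A hypothesis was that such peaks include recruitment sites of the dosage compensation complex, which binds X in hermaphrodite embryos at sites that hold the 12-base element TCGCGCAGGGAG. Sequences within 2 mismatches of it occurred in 10 of 102 thresholded windows of X and 8 of 594 of the autosomes (odds ratio 7.96, 95% interval 3.09 to 19.9, Fisher's exact test, p = 4.78e-05). Within bins of G+C the odds ratio was 9.58 (95% interval 3.64 to 25.2), and in replicates 1 and 2 alone it was 9.93 and 9.37. Among lower pooled peaks X and the autosomes had 0.193% and 0.2001% (odds ratio 0.964, exact p = 1). The 10 X peaks ranked from 23 to 309. They included intergenic peaks at 11094054 to 11094397 (1 mismatch, GTCCCTGCGCGA on the plus strand at 11094224 to 11094235) and 806631 to 806721 (1 mismatch), an intronic peak at 2996951 to 2997294 (0 mismatches, CTCCCTGCGCGA, the reverse complement of the element, at 2997121 to 2997132) and an intergenic peak at 8036268 to 8036611, 4873 bp from the start of xol-1, a gene of sex determination. Of the 5 high X peaks far from a start that prompted the test, 2 held such a sequence, and the 2 highest and the peak at 13700665 to 13701008 did not. This is consistent with part of the X list being such recruitment sites, and leaves those without the sequence unaccounted for. Whether PAX-1 itself was bound there, or whether the sites are enriched in unrelated immunoprecipitations too, was not tested.

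Thresholded peaks at 39 of 110 ribosomal protein, proteasome and chaperone genes (35.5%, against 4.73% of other genes) gave an odds ratio of 11.1. For the 3 lists joined, neither G+C content nor distance to the start accounted for this alone: within G+C bins the odds ratio was 6.66 (95% interval 4.19 to 10.6) and within distance bins 9.42 (6.23 to 14.2). The lists were joined because they had passed above, and 25 of the 39 genes were ribosomal protein genes. Neither the proteasome nor the chaperone list was tested alone within bins, so this does not extend to them. GTCACG was in 0 of 39 windows of the 3 lists and 31 of 366 other proximal thresholded windows (odds ratio 0, upper bound 2.25, Fisher's exact test, p = 0.0586), which leaves open whether its share differed. Of the whole peaks 2 of 39 held it (5.13%, exact 95% interval 0.627% to 17.3%), against 42 of 366 others (11.5%, Fisher's exact test, p = 0.289). Most of these peaks thus held no exact core, and the comparison does not decide whether they held it less often than the others. Degenerate sites were not searched, and immunoprecipitation background at highly transcribed genes stays open, since no expression values or untagged samples were analysed here.

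The absence of pooled peaks around pax-1 might come from extra copies of the transgene region in the control libraries. The stretch of 51.43 kb exceeded the 99th percentile on chromosome V (27.8 kb), and neither replicate had a peak in its central 50%. But 4 stretches on chromosome V and 14 in the genome were longer, so stretches of this length also lie away from pax-1 and the test leaves the question open. An excess of masked sequence is argued against: 24.7% of its bases were soft-masked, below the median of 30.8% for stretches of that length on the chromosome. How uniquely reads map there was not measured.

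Mitochondrial DNA carried 18 thresholded peaks, 15 of them among the 100 highest, and 16 of the 18 overlapped no peak of replicate 1, which had 2 mitochondrial peaks against 25 in replicate 2. More mitochondrial DNA in replicate 2 than in the control may explain these, and would spread peaks over the molecule. The peaks of replicate 2 covered 47.9% of it, against 3.55% in replicate 1, and their largest gap was 1892 bp, between the median (1476 bp) and the 95th percentile (2225 bp) of random places, which does not decide. Whether the 2 peaks shared with replicate 1 have the same source was not tested.

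Among the 10 hexamers with the smallest p, 6 chained into AGAGACGCAGA, which occurred in 64 of 713 thresholded windows (8.98%) and 3.07% of matched background windows, counted on the same data. A hypothesis was that 1 longer sequence lay behind several hexamers. The word assembled from chromosomes I, II and III was a different sequence, GCGCGCTCC, found in 4 of 302 thresholded windows and 6 of 1499 background windows of IV, V and X (odds ratio 3.34, 95% interval 1.03 to 11.6, Fisher's exact test, p = 0.0705). Both 8-base parts of the word were more frequent there, CGCGCTCC in 12 against 18 windows (odds ratio 3.40, 95% interval 1.66 to 7.14, exact p = 0.00196) and GAGCGCGC in 9 against 17 (odds ratio 2.68, 95% interval 1.23 to 6.10, exact p = 0.0287). These p are unadjusted and the parts overlap, so a shared longer sequence stays open.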
